A study of Mus musculus with 6 samples.

How the data were processed

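The series holds 6 chromatin immunoprecipitation sequencing (ChIP-seq) samples of mouse embryonic stem cells that carry a GFP knock-in at Rx, an eye-field transcription factor gene, and were kept in 2i+LIF medium. The cells lacked endogenous Wdr5 and p53 and were rescued with wild-type WDR5 (WT rescue) or with WDR5 carrying the substitutions S91K and Y191F (mutant rescue), numbered as in the labels. In each of the 2 lines 1 WDR5 library, 1 H3K4me3 library and 1 input library were made, after 10 minutes in 1% formaldehyde per the labels' protocols. The 4 peak lists of the antibody libraries were analysed. The 2 input libraries were not analysed here.

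Per the submitters' processing notes, reads were handled with BWA 0.7.17-r1188, SAMtools, Picard and MACS2 2.1.2 on the mm10 build; those notes give neither the settings nor the control used for each list. Each deposited list belongs to 1 library, and no pooling of libraries is recorded. The deposited lists give for each peak a position, a fold enrichment at the summit, a −log10 p, a −log10 q, a score and a summit position, all in the authors' units. The smallest −log10 p in the deposited lists was 2.00, so the authors' threshold admitted peaks whose −log10 q was near 0. The fold is the authors' own value for that peak, and it was used only to describe, rank or filter peaks within a list. The deposited score was not used. Read depth is unknown, because peak lists carry no read totals, and the width and number of peaks depend on that depth.

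Rows of a list that overlapped by at least 1 bp were joined into regions; no rows overlapped, so regions and deposited rows are the same in number. Overlap between lists was taken with bedtools 2.31.1 at a minimum of 1 bp, in both directions. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Chance overlap was measured from 100 placements of the regions at random positions of the same chromosome, within the span that the lists cover. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

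Genes came from a RefSeq gene table on GRCm38.p6, whose coordinates are those of mm10. The plan was to use annotated transcription start sites. The table gives no strand, so a gene counted as occupied when a region lay within 1 kb of either annotated gene end, here called a gene boundary, and a region at the downstream end is therefore counted too. Base composition and motifs at WDR5 summits had been planned and were not run, because no genome sequence was used here. The gene code was tested on simulated data for the comparison of WDR5 gene boundaries over 21887 protein-coding genes: it found 200 of 200 genes with a planted region and 80 of 80 planted in a single list, and 10 of 200 random lists fell in the highest 5% of draws.

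With 1 library per antibody and line, no test between lines was made and no p-value is given. The presence of regions was described, and a difference between the lines has no replicate check. For 18 gene lists fixed before the data were examined, the number of occupied members was set beside 10000 random lists of protein-coding genes of the same size. For WDR5 these were matched on an H3K4me3 region at a boundary in either line, and for H3K4me3 they were unmatched. The list of polymerase III and structured non-coding RNAs holds no protein-coding gene and has no random lists. The other lists cover naive pluripotency, formative and primed pluripotency, neuroectoderm and eye field, mesoderm, endoderm, Hox genes, KMT2/SETD1 complex subunits, p53 targets, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, histones, nucleolar and translation factors, glycolysis, fibroblast (feeder) markers, trophectoderm, 2-cell-like genes and olfactory receptors. The histone list was written for replication-dependent genes, but its name pattern also takes in variants such as H2az1.

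The genes named were set by a rule written beforehand. For each antibody these are the 10 protein-coding genes with the highest fold at a gene boundary in the WT rescue list among genes occupied in both lines, the 10 highest occupied in the WT rescue only and the 10 highest in the mutant rescue only, with 1 gene per region. The rule adds the 5 strongest regions of each list, Wdr5 and Trp53, and up to 4 members of each gene list per class by fold. Some genes that the rule takes are not reported here. Transfer RNA genes, RNA methylation genes and single chromosomes were singled out after their values were seen. Alternatives fixed before the data were examined were a −log10 q of at least 2, a −log10 p of at least 5, lists of equal length, a reciprocal overlap of 50%, chromosomes 1 to 19 and X, a window of 2.5 kb and all annotated genes. Alternatives added after seeing the data were gene boundaries with H3K4me3 in both lines, removal of regions 270 to 290 bp wide with a fold of at least 5, removal of regions within 200 bp of a transfer RNA gene, and the counts of transfer RNA genes. Intervals for the median fold on X were taken from 10000 bootstrap draws of its regions and, exactly, from order statistics. The read depth prediction was taken as not met in a list only where both lay below the highest autosome. Neither interval counts the spread of that autosome's own median.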

Results

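WDR5 is a WD-repeat scaffold protein shared by the KMT2/SETD1 methyltransferase complexes, which place methyl groups on lysine 4 of histone H3. The trimethylated form, H3K4me3, is found at many promoters, and its presence alone does not show that a gene is active. WDR5 and H3K4me3 were mapped by ChIP-seq in mouse embryonic stem cells without endogenous Wdr5 and p53 that had been rescued with wild-type WDR5 or with WDR5 carrying S91K and Y191F. The comparison asks where WDR5 and H3K4me3 regions were listed in each line. The WDR5 lists held 11095 regions in the WT rescue and 26888 in the mutant rescue, with median widths of 204 and 197 bp, and covered 2743 and 6038 kb. The H3K4me3 lists held 71695 and 74305 regions, with median widths of 744 and 726 bp. In the WDR5 lists 10.8% of the WT rescue regions and 4.83% of the mutant rescue regions had a −log10 q of at least 2, against 94.0% and 90.7% for H3K4me3. There was 1 library per antibody and line, so no difference between the lines has a replicate check.

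The targeted genes were examined first. Wdr5 (chromosome 2, 27515147 to 27536535, mm10) had an H3K4me3 region over its lower-coordinate end in both lines, from 27514505 to 27516491 in the WT rescue and from 27514649 to 27516417 in the mutant rescue. Inside the gene each H3K4me3 list held 3 further regions at nearly the same positions, of 653, 610 and 266 bp in the WT rescue and 643, 610 and 267 bp in the mutant rescue. A WDR5 region of fold 2.35 lay over the same end of Wdr5 in the WT rescue list alone, with a −log10 q of 0. Further WDR5 regions lay at the internal H3K4me3 regions, at 27520763 (fold 1.57, −log10 q 0) in the WT rescue and at 27534706 (fold 1.80, −log10 q 0.622) in the mutant rescue. Trp53, which encodes p53 (chromosome 11, 69580348 to 69591873), had an H3K4me3 region at its lower-coordinate end in both lines, starting at 69580347 in the WT rescue and at 69580296 in the mutant rescue. Peak lists do not show whether a gene's coding sequence is intact, so these regions do not check the knockouts.

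Genes of the translation machinery were the most numerous among the shared WDR5 genes of highest fold. Of the 10 shared genes with the highest fold in the WT rescue list, 4 encode cytosolic ribosomal proteins (Rps6, Rpl38, Rpl36 and Rpl7a) and a further pair the elongation factors Eef2 and Eef1g. The others included the RNA demethylase gene Alkbh5 and the histocompatibility genes H2-D1 and H2-DMa. Rps6 had a region on chromosome 4 from 86856587 to 86857809 with a fold of 17.1 in the WT rescue list and a region of fold 14.3 in the mutant rescue list, each fold being the authors' value within its own list. For Eef2, on chromosome 10 from 81176415 to 81177383, the folds were 17.1 and 8.70. Alkbh5 had the highest WT rescue fold among these shared genes, 30.9, but held 5 regions of fold at least 5 along the gene, and the H2-D1 region was a narrow one of 276 bp.

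Across protein-coding genes, 3574 of 21887 (16.3%) had a WDR5 region at a gene boundary in the WT rescue and 2344 (10.7%) in the mutant rescue. Both lists held 948 genes, against 383 for independent lists of these sizes. Random placement gave means of 418.8 and 965 genes. A further 2626 genes were in the WT rescue list alone and 1396 in the mutant rescue list alone. These counts depended on the threshold and on list length. With a −log10 q of at least 2 they were 514 and 377 genes, of which 180 were in both lists. Of the 334 and 197 genes then in a single list, 92 (27.5%) and 90 (45.7%) had their region overlapped by a region of the other line. With lists of equal length the mutant rescue count was 1365.

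The genes with the highest fold in the WT rescue WDR5 list alone were Xylt2 and Ripply3, each at a narrow region of 283 bp, and Ddx11, a DNA helicase gene. Next came Prxl2a, Meaf6 (a subunit of histone acetyltransferase complexes), the DNA repair gene Mgmt, Rprm, Ppfia1, the chromatin remodeller gene Smarcad1 and Mepce, which encodes the enzyme that caps 7SK RNA. Their folds ran from 6.25 for Xylt2 to 4.59 for Mepce. The regions of Ddx11 and Mepce were overlapped by a mutant rescue region lying outside the 1 kb window. In the mutant rescue list alone the highest were the arginine methyltransferase gene Prmt5 (fold 10.8), the angiogenin gene Ang (10.6), Mrpl58 (9.82), the respiratory complex I gene Ndufs7 (8.84), Fbxo31 (8.76), Btn1a1 (8.05), Ankar (7.61), the clock gene Per1 (7.53), the proteasome gene Psma3 (7.44) and Ilf2 (6.62). Every gene of these 10 except Ankar had its region within 200 bp of a transfer RNA gene, as with the Prmt5 region on chromosome 14 from 54517236 to 54517905. Over the whole class this held for 22 of 1396 genes (1.58%), and for 37 of 197 (18.8%) with a −log10 q of at least 2. Ankar's region was overlapped by a WT rescue region.

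Cytosolic ribosomal protein genes were the group with the highest share of WDR5 regions among the 18 lists in either line. Of 78 genes, 60 had a region in the WT rescue and 54 in the mutant rescue, with 50 in both, while matched random lists had medians of 18 and 11 and 0% of them reached these counts. With a −log10 q of at least 2 the counts were 44 and 44, with 41 genes in both. Rpl4, Rplp1 and Rps25 were among the members in the WT rescue alone, and Rps29, Rpl18, Rps12 and Rpl23a led those in the mutant rescue alone. The Rps29 region (−log10 q 13.5) also lay at the RNA gene Rn7s1. The regions of Rpl18, Rps12 and Rpl23a had a −log10 q of 0.958, 0.0171 and 0.110. Nucleolar and translation factor genes followed, with 15 of 24 in the WT rescue, a count reached by 0.01% of random lists, and 5 in the mutant rescue, reached by 19.97%. Eef2, Eef1g, Rack1 and Eef1a1 were in both lists, whereas Ncl (nucleolin), Eef1b2, Fbl (fibrillarin) and Tpt1 led those in the WT rescue alone. At a −log10 q of at least 2 this list had 7 and 3 members, counts reached by 0.01% and 1.58% of random lists. Of 78 mitochondrial ribosomal protein genes, 16 and 11 had a region, near the random medians of 17 and 10.

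Pluripotency and lineage genes had WDR5 regions at a minority of their members. Of 25 naive pluripotency genes, 6 had a region in the WT rescue and 0 in the mutant rescue, beside random medians of 5 and 3; 3.32% of random lists had as few in the mutant rescue. The WT rescue members led with Sox2, Utf1, Tfcp2l1 and Klf2, at folds of 3.63, 3.13, 2.89 and 2.69, and 1 of the 6 remained at a −log10 q of at least 2. Of 15 formative and primed genes, 5 and 3 had a region, with Lin28b, Etv4 and Pou3f1 in both and Zic2 and Foxd3 in the WT rescue alone, beside random medians of 3 and 2. At a −log10 q of at least 2 the formative and primed counts were 3 and 0, and 1.06% of random lists reached the WT rescue count. Neuroectoderm and eye-field genes gave 2 and 3 of 18, with Nes, an intermediate filament gene of neural progenitors, in both. Mesoderm genes gave 0 and 2 of 18 (T and Mesp2; 1.19% of random lists had as few as in the WT rescue), endoderm genes 2 and 0 of 12 (Cxcr4 and Lama1), and Hox genes 4 and 5 of 39, with Hoxa4 and Hoxb2 in both (4.68% had as few as in the WT rescue). Trophectoderm genes gave 1 and 1 of 8 (Ascl2 and Cdx2), and the 2-cell-like genes 0 and 0 of 7. At a −log10 q of at least 2 the neuroectoderm, mesoderm, endoderm and trophectoderm lists each had 0 and 0 members with a region and the Hox list 1 and 1.

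Among the remaining groups, KMT2/SETD1 subunit genes had WDR5 regions at 7 of 20 members in the WT rescue and 2 in the mutant rescue. Matched random lists had medians of 4 and 2. Ncoa6 was in both lists, Wdr82, Kmt2a, Psip1 and Wdr5 were among those in the WT rescue alone, and Dpy30 was in the mutant rescue alone. Targets of p53 gave 8 and 5 of 24, beside random medians of 5 and 3, with the ribonucleotide reductase gene Rrm2b, Ccng1 and the apoptosis gene Bax in both. Histone genes gave 24 and 12 of 75 at the authors' threshold, and 1 and 3 at a −log10 q of at least 2. At the authors' threshold their random medians were 15 and 9, and 1.1% of random lists reached the WT rescue count. Neighbouring histone genes can share 1 region, as H2ac15 and H2bc15 did, so random lists of scattered genes are a loose comparison for them. The mutant rescue region of H4c8, from 23530204 to 23530705 on chromosome 13 (−log10 q 12.0), lay over a transfer RNA gene. Glycolysis genes gave 4 and 3 of 13, beside random medians of 3 and 2, with Pgk1 and Pgam1 in both. The WT rescue region of Pgk1, from 106203630 to 106203866, lay at the gene's higher-coordinate end, inside an H3K4me3 region of 377 bp. Pgk1 was the only glycolysis gene left at a −log10 q of at least 2 in either list. Under a −log10 q cut of 2 the counts were 2 and 1 for KMT2/SETD1 subunit genes, 1 and 0 for p53 targets and 1 and 1 for glycolysis genes. Fibroblast markers, which would show feeder cells, gave 0 and 1 of 13 (Thy1), beside random medians of 2 and 1. Olfactory receptor genes, a silent control, had regions at 11 of 1110 members in the WT rescue and 49 in the mutant rescue, beside random medians of 21 and 50. With a −log10 q of at least 2 they had regions at 1 and 0 members. Of 10 polymerase III and structured RNA genes, 0 and 2 had a region: Rn7s1, the RNA of the signal recognition particle, and Rnu11. The Rn7s1 region, on chromosome 12 from 69158973 to 69159441, is the same region that was counted for Rps29.

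**Figure D1:**
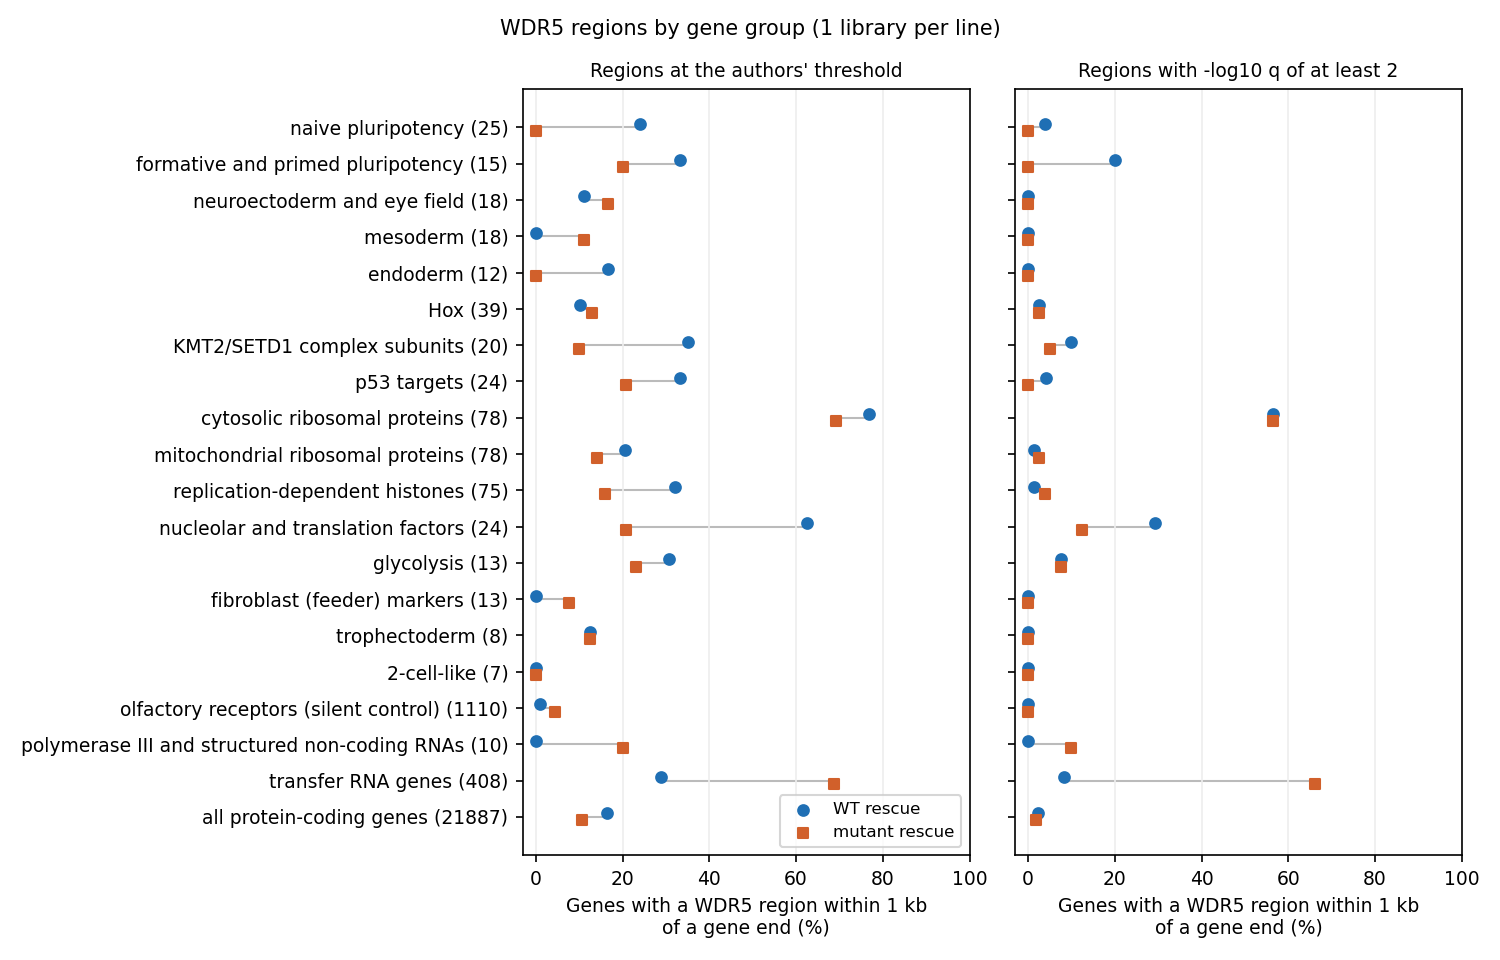
Share of each gene group, in %, with a WDR5 region within 1 kb of a gene end in the WT rescue (blue circles) and the mutant rescue (orange squares), with group sizes in parentheses and 1 library per line. The left panel uses all regions and the right those with a −log10 q of at least 2, where transfer RNA genes stood at 8.33% and 66.2% and 44 of 78 cytosolic ribosomal protein genes had a region in each line.

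Transfer RNA genes, a class singled out after its values were seen, had far more WDR5 regions in the mutant rescue list. Of 408 genes, 118 (28.9%, interval 24.6 to 33.6%) had a region within 1 kb in the WT rescue and 280 (68.6%, 63.9 to 73.1%) in the mutant rescue, with 117 in both. Random placement gave means of 4.03 and 10.2. With a −log10 q of at least 2 the counts were 34 (8.33%, 5.84 to 11.5%) and 270 (66.2%, 61.4 to 70.8%), and all 34 were in both. H3K4me3 regions lay at 290 and 291 of these genes. Regions within 200 bp of a transfer RNA gene made up 1.34% of the 1197 WT rescue regions and 15.5% of the 1299 mutant rescue regions with a −log10 q of at least 2. The highest fold among the mutant rescue regions, 12.5, was at n-TAagc12 and n-TVaac2 on chromosome 13 from 23400734 to 23401568, where the WT rescue list had no region. At n-THgtg3 and n-THgtg5 on chromosome 2, from 122377174 to 122378199, both lists had a region.

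**Figure D2:**
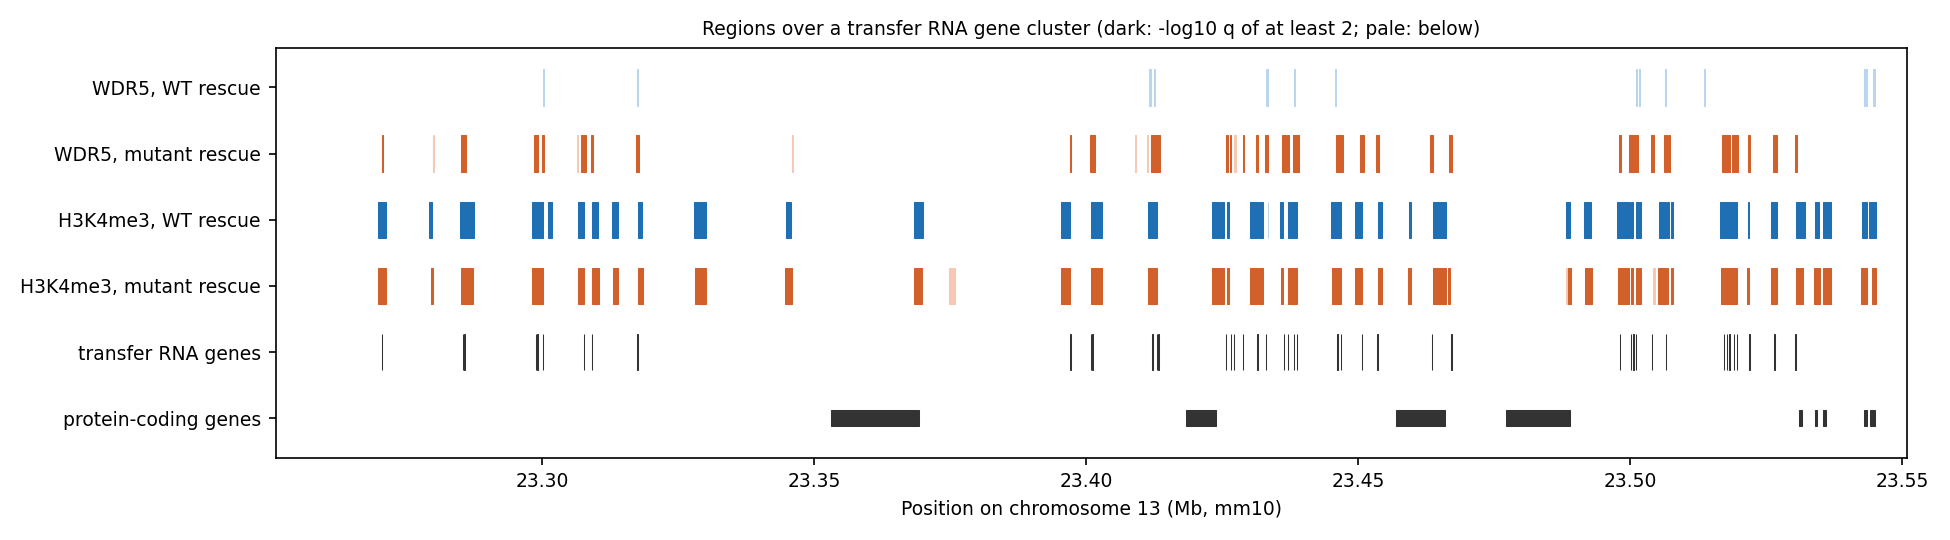
Map of chromosome 13 from 23250942 to 23550942 (mm10, axis in Mb), centred on the transfer RNA region with the highest fold in the mutant rescue WDR5 list, with regions of the 4 lists as boxes (dark at a −log10 q of at least 2, pale below) above transfer RNA and protein-coding genes. The window holds 45 transfer RNA genes and, at these genes or elsewhere, 39 mutant rescue WDR5 regions, 33 of them at a −log10 q of at least 2, and 13 WT rescue WDR5 regions, of which 0 reached it.

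WDR5 regions were shared between the lines mainly at the top of each list. Of the WT rescue regions, 12.3% (11.7 to 12.9%) were overlapped by a mutant rescue region, and of the mutant rescue regions 5.09% (4.83 to 5.36%) were overlapped in the other direction, against 0.522% and 0.216% by random placement. In the most significant decile of each list the shares were 54.8% and 29.7%, and in the least significant decile 4.87% and 1.53%. With a −log10 q of at least 2 they were 38.4% and 35.5%. In the WT rescue the 5 highest folds were at regions of 280 to 283 bp, inside Hdac8, Ube2e2, Arl15 and Adgrb3 and on chromosome 9 from 97324441 to 97324723, all overlapped in every list. In the mutant rescue the 5 highest began with the same chromosome 9 region and the Ube2e2 region. Then came regions of 1790 bp inside Ythdf3 and 1783 bp inside Ythdf1, whose products bind methylated RNA. The last was a 281 bp region on chromosome 4. All 5 were overlapped in every list, both H3K4me3 lists included.

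H3K4me3 regions were largely shared. Of the WT rescue regions 80.7% (80.4 to 81.0%) were overlapped in the mutant rescue and of the mutant rescue regions 77.7% (77.4 to 78.0%) in the WT rescue, against 4.96% and 4.84% by random placement. The share was 100% in the most significant decile of both lists, and 45.9% and 36.3% in the least significant. The 5 highest folds in the WT rescue lay inside Chl1, on chromosome 12 from 3109862 to 3110121, on chromosome 9 from 105115978 to 105116260, at the boundary of Ext2 and inside Hs3st2. In the mutant rescue the first 4 of these places were followed by a region inside Col6a5. All were 260 to 283 bp wide.

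**Figure D3:**
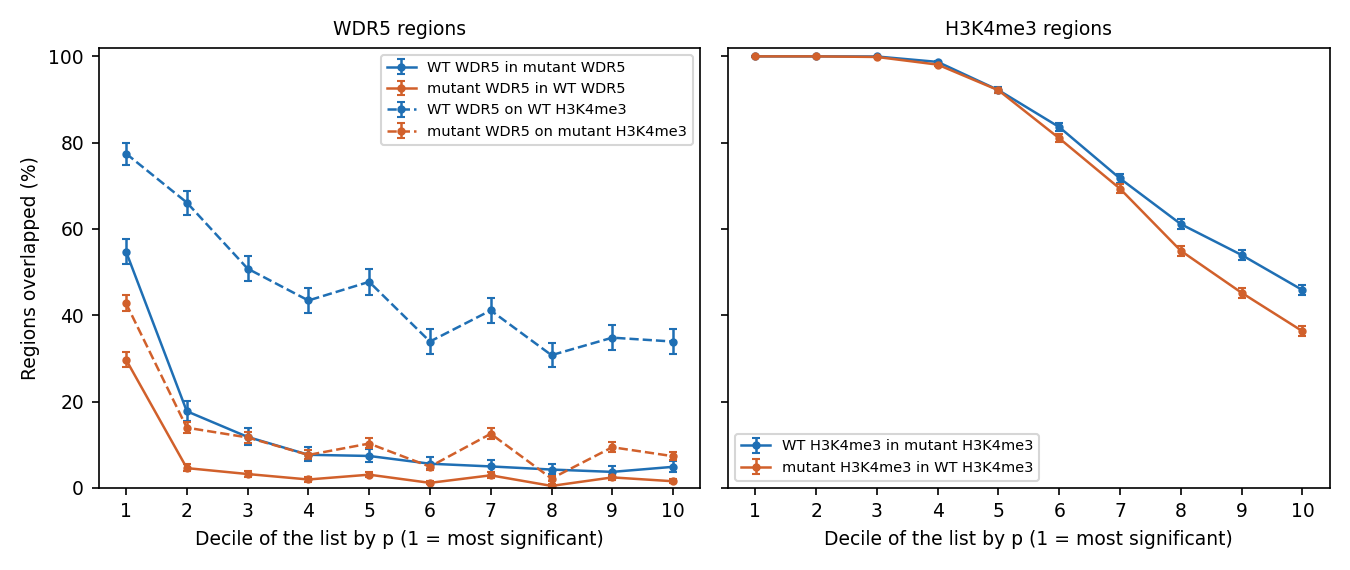
Share of regions overlapped by another list, in %, against the decile of the list by −log10 p (1 is the most significant, ties ordered by fold), with exact 95% binomial intervals as bars; solid lines give overlap between the lines and dashed lines WDR5 on H3K4me3 in the same line. Overlap of WDR5 between the lines was 54.8% and 29.7% in the first decile, and that of H3K4me3 was 100% in both directions.

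At gene boundaries, 14978 protein-coding genes had an H3K4me3 region in the WT rescue and 14797 in the mutant rescue, and 14575 were in both. Another 403 were in the WT rescue alone and 222 in the mutant rescue alone. The shared genes of highest fold were Ext2, whose region was a narrow one of 277 bp, Pgk1, Bpi, Gm3417, Zfp979, Gm17353, Zxdb, Lars2, Srp54c and Gm2956, with WT rescue folds from 59.4 to 31.9. Those of the WT rescue alone were led by the glutamate receptor gene Grik2, 1700017N19Rik, the vitronectin gene Vtn, Acot3, Pogz, Ano2, Errfi1, Spx, Pcdhb20 and Supv3l1. All of them except Ano2 had a region that a mutant rescue region overlapped, so that the lines differed there in where the region ended and not in its presence. The same held for all 10 named genes of the mutant rescue alone, Ddo, the glucagon receptor gene Gcgr, Prss46, Xlr5b, Mrpl24, Gria2, Gckr, Dock11, Gm51792 and Pcmtd1. Over the whole classes, 65 of 403 and 37 of 222 genes were of this kind. Ano2 had a region of fold 12.7 on chromosome 6 from 125690061 to 125690910 in the WT rescue alone.

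H3K4me3 regions were present at most members of nearly all groups in both lines. Of all protein-coding genes, 68.4% had one at a boundary in the WT rescue and 67.6% in the mutant rescue. The counts in the WT and the mutant rescue were 23 and 23 of 25 naive, 14 and 14 of 15 formative and primed, 18 and 17 of 18 neuroectoderm, 17 and 16 of 18 mesoderm, 8 and 7 of 12 endoderm and 36 and 34 of 39 Hox genes. They were 19 and 19 of 20 KMT2/SETD1 subunit genes, 23 and 22 of 24 p53 targets, 78 and 77 of 78 cytosolic and 75 and 76 of 78 mitochondrial ribosomal protein genes, and 65 and 65 of 75 histone genes. Nucleolar and translation factors gave 23 and 23 of 24, glycolysis genes 12 and 12 of 13, trophectoderm genes 7 and 7 of 8 and polymerase III and structured RNA genes 9 and 9 of 10. The endoderm counts lay near their random medians of 8 and 8. Random lists reached the trophectoderm counts in 22.8% and 21.7% of draws and the glycolysis counts in 5.33% and 4.51%. For the other lists of protein-coding genes named so far the share was at most 4.06%. The members in a single list included Six3, Bmp4, Afp, Hoxc4, Hoxa9, Hoxd11, Eda2r and Rpl17 in the WT rescue and Hoxd10 and Mrpl24 in the mutant rescue. With a 2.5 kb window all members of the neuroectoderm, mesoderm, Hox and both ribosomal protein lists had H3K4me3 in both lines. Fibroblast markers gave 8 and 5 of 13, with the collagen gene Col1a1, the smooth muscle actin gene Acta2 and Prrx1 in the WT rescue alone. Their random medians were 9 and 9, and 2.97% of random lists had as few in the mutant rescue. With a 2.5 kb window the fibroblast markers gave 9 and 8. The 2-cell-like genes gave 0 and 1 of 7 (Tdpoz4), beside random medians of 5 and 5. Olfactory receptors gave 34 and 33 of 1110, beside random medians of 760 and 750.

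WDR5 regions lay on H3K4me3 regions of the same line far more often than random positions did. In the WT rescue 46.0% (45.1 to 46.9%) of WDR5 regions overlapped H3K4me3 and in the mutant rescue 12.3% (11.9 to 12.7%), with 3.29% and 3.23% by random placement. Among regions with a −log10 q of at least 2 the shares were 76.2% (73.7 to 78.6%) and 64.7% (62.1 to 67.3%), and with lists of equal length they were 46.0% and 19.03%. Protein-coding gene boundaries held 30.4% of WT rescue and 8.33% of mutant rescue WDR5 regions, and 37.1% and 25.3% of those with a −log10 q of at least 2. When at least 50% of each region had to overlap, the shares on H3K4me3 were 3.97% and 1.87%.

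H3K4me3 was present at nearly all genes whose WDR5 region was in the WT rescue list alone, in both lines. Of these 2626 genes, among them Meaf6, Mgmt and Smarcad1, 97.3% (96.6 to 97.9%) had an H3K4me3 region in the WT rescue and 97.3% (96.6 to 97.9%) in the mutant rescue. Of the 948 genes with WDR5 in both lines, such as Rps6 and Eef2, 99.3% and 99.2% had H3K4me3. Of the 1396 with WDR5 in the mutant rescue alone, such as Prmt5 and Ndufs7, the shares were 79.9% (77.7 to 82.0%) and 79.5% (77.3 to 81.6%). Of the 16917 genes with WDR5 in neither list, 61.3% and 60.2% had H3K4me3. Presence in a list does not measure the amount of H3K4me3, which was not compared between the lines.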

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

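No test was run on the values in this part. Signal lay on unplaced scaffolds, which no gene comparison used: 69 WDR5 regions in the WT rescue and 74 in the mutant rescue, and 126 and 125 H3K4me3 regions. No control list was used here to set a background for them.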

How the results depend on the processing

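Settings chosen only after the results were seen were the removal of narrow regions, the removal of regions at transfer RNA genes, the gene boundaries with H3K4me3 in both lines, and all counts of transfer RNA genes; the rest were fixed beforehand. No paired analysis was possible because each antibody has 1 library per line and no result comes from a test. Base composition and motifs at WDR5 summits, with their alternatives, were not run, since no genome sequence was used here. Of the values that answer a comparison, 72 moved beyond their interval, or by over 1.5 times for a count, and 71 did not; of the gene list counts 75 moved and 213 did not. Depth is unknown, and the WDR5 lists hold mostly regions of low significance, so their counts depend on where each list stops. Restricting to chromosomes 1 to 19 and X was run on the 6 shares of overlapping regions and moved none of them beyond its interval.

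With a −log10 q of at least 2, WDR5 genes numbered 514 in the WT and 377 in the mutant rescue (180 both, 334 and 197 in a single list). Shared WDR5 regions were 38.4% and 35.5%, WDR5 on H3K4me3 76.2% and 64.7%, and shared mutant rescue H3K4me3 regions 80.2%. H3K4me3 in the WT and mutant rescue lists was present at 98.3% and 98.3% of genes with WDR5 in both, 98.5% and 98.8% in the WT rescue alone, 92.9% and 92.9% in the mutant rescue alone and 67.2% and 66.1% in neither. Transfer RNA genes in the WT rescue were 34. With a −log10 p of at least 5, WDR5 genes were 1028 and 605 (264 both, 764 and 341 single). Shared WDR5 regions were 27.3% and 22.5%, WDR5 on H3K4me3 71.9% and 42.9%, and shared H3K4me3 regions 80.1% and 83.1%. H3K4me3 by class was 98.8% and 98.8% (WT rescue alone), 89.7% and 90.0% (mutant rescue alone) and 65.9% and 64.4% (neither), and transfer RNA genes in the WT rescue were 51. In both settings fewer regions enter by construction.

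With lists of equal length, shared WDR5 regions were 9.82% and 9.76%, mutant rescue WDR5 on H3K4me3 19.03%, mutant rescue WDR5 genes 1365, of which 685 in that list alone, and shared H3K4me3 regions 79.8% and 79.4%. With 50% reciprocal overlap, shared WDR5 regions were 7.73% and 3.19%, shared H3K4me3 regions 64.1% and 61.9%, and WDR5 on H3K4me3 3.97% and 1.87%, where the wider H3K4me3 regions set a limit by construction.

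With a 2.5 kb window, 2162 genes had WDR5 in the mutant rescue alone; H3K4me3 by class was 96.4% and 96.2% (WT rescue alone), 77.2% (mutant rescue alone, mutant list) and 65.5% and 65.0% (neither). With all annotated genes, mutant rescue WDR5 genes were 4000, of which 2666 in that list alone, and single-list H3K4me3 genes 1214 and 957. H3K4me3 by class was then 98.4% (both, WT list), 92.9% and 92.5% (WT rescue alone), 63.9% and 64.0% (mutant rescue alone) and 38.0% and 37.4% (neither). At boundaries with H3K4me3 in both lines, 930 genes had WDR5 in the mutant rescue alone. Without narrow regions, shared WDR5 regions were 11.5% and 4.74%, and without regions at transfer RNA genes mutant rescue WDR5 on H3K4me3 was 11.6%. Within 200 bp, 77 transfer RNA genes had WDR5 in the WT rescue. For moves not set by construction the cause was not tested.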

Other observations

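All tests in this part were chosen after the results were seen except the read depth test of chromosome 8, which was written beforehand as a single statement with X; the division by chromosome, and for X by list with intervals, came afterwards. Other RNA gene classes did not share the contrast seen at transfer RNA genes. With a −log10 q of at least 2, WDR5 regions lay at 28 of 1340 small nucleolar RNA genes in the WT rescue and 28 in the mutant rescue, with 23 in both. The counts were 99 and 108 of 12727 long non-coding RNA genes, 6 and 8 of 1228 microRNA genes and 7 and 5 of 1004 small nuclear RNA genes. Transfer RNA genes of chromosome 13 had regions of that significance at 0 of 105 genes in the WT rescue and 100 in the mutant rescue, and those of chromosome 6 at 0 and 3 of 53.

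The first pattern is the excess of transfer RNA genes in the mutant rescue WDR5 list. A longer list is argued against, because among the same number of most significant regions in each list the ratio of mutant to WT rescue genes was 7.88 (268 against 34). A general rise of signal at the most occupied genes is argued against by cytosolic ribosomal protein genes, where the ratio was 1 (44 and 44). Transfer RNA genes being read differently in the 2 lines stays open, although their H3K4me3 ratio was 1.00 (290 against 289). Of 408 transfer RNA genes, 286 had H3K4me3 regions in both lines and 122 did not. Of the 270 with a mutant rescue WDR5 region at a −log10 q of at least 2, 259 were among the 286. At those genes H3K4me3 was present in both lists by definition, and its amount was not compared. Also open are a difference between the 2 WDR5 libraries themselves, since each line has 1 and the inputs were not analysed here, and an effect of the substitutions, which was not tested.

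The second pattern is regions of high fold inside a few genes. All 5 WT rescue WDR5 regions with a fold of at least 20 that were not 270 to 290 bp wide lay in RNA methylation genes, Ythdf3, Ythdf1, Alkbh5, Ythdf2 and Mettl3, as did 2 of 2 in the mutant rescue, and Alkbh5 and Mettl3 held 5 and 8 WT rescue regions of fold at least 5, as many as Alkbh5 being reached by 0.00914% of protein-coding genes. Most of the regions of fold at least 5 in these genes lay more than 1 kb from any annotated end of a protein-coding gene. By position, binding at those ends does not account for them. These genes were singled out for strong regions inside them, and regions of 1 gene are not independent. Mettl3 and Alkbh5 alone held 8 and 5 of the 17 in the WT rescue. The shares below therefore describe these regions only and decide nothing further about promoter binding. Of these regions 23.5% (4 of 17) lay within 1 kb of the end of any protein-coding gene in the WT rescue and 1 of 10 in the mutant rescue. Over all regions of that fold that were not 270 to 290 bp wide, the shares were 47.3% (89 of 188) and 38.3% (116 of 303). Promoters inside the genes were not looked at. The mutant rescue regions of highest fold in Ythdf3 and Ythdf1 were overlapped in every list, both H3K4me3 lists included. Wdr5 held 3 H3K4me3 regions of 250 to 700 bp with a fold of at least 10, lying 300 bp or more from the gene ends and with edges within 10 bp in both lines, a count reached by 0.00457% of protein-coding genes. These filters and counts were set from Alkbh5 and Wdr5 themselves, so the low shares decide nothing about construct or cDNA sequence in the libraries, which stays open; exon positions, which would bear on it, were not used here.

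The third pattern is the spread of WDR5 regions over chromosomes. Chromosome 8 held 7.69 regions per Mb in the WT rescue and 14.6 in the mutant rescue, above the other autosomes (at most 6.68 and 12.4), and X held 0.405 and 0.620. The H3K4me3 lists leaned the same way. In both of them chromosome 8 ranked 18 from the lowest of 19 autosomes in regions per Mb. X held 13.2 and 13.8 H3K4me3 regions per Mb, against at least 22.8 and 23.6 on the autosomes. Gene density is argued against in the WT rescue. For the 8.26 protein-coding genes per Mb of chromosome 8, a line over the other autosomes gives 4.27 regions per Mb (interval of the line's mean 3.97 to 4.56). Chromosome 8 stood at 1.80 times that value. In the mutant rescue it stood at 1.34 times the line's value (10.8, interval of the line's mean 10.3 to 11.4). The mutant rescue line was flat (slope 0.00109, interval −0.203 to 0.206), so it carries no expectation from gene density and decides nothing there. The wider interval for a further chromosome was 2.15 to 6.39 in the WT rescue, and chromosome 8 lay above it. In the mutant rescue that interval was 7.02 to 14.63, and chromosome 8 lay inside it at 14.56. Scatter between chromosomes is therefore not excluded in the mutant rescue. By the measure first used, regions per gene, chromosome 8 stood at 1.43 and 0.973 times the highest other autosome. A higher copy number of chromosome 8 may contribute. Its median fold at a −log10 p from 2 to 3 ranked 1 from the lowest of 19 autosomes in both WDR5 lists, though it ranked 4 in both H3K4me3 lists. That ranking leaves out X. The median on X was below that of chromosome 8 in the WT rescue WDR5 list (2.04 against 2.18). In the mutant rescue WDR5 list it was above (2.11 against 2.08). X was sparse in both lists, so a low median fold alone does not show a higher copy number. For X, the prediction was that lower depth calls for a higher fold than on any autosome. The ratio to the highest autosome was 0.866 in the WT rescue (exact interval of the median 0.818 to 0.982, 12 regions), where the prediction was not met. The ratio was 0.933 in the mutant rescue (0.915 to 1.03, 34 regions), where the prediction stays open. The statement as first written was therefore not met as a whole. Read depth is not excluded by this in either list. The intervals leave out the spread of the highest autosome, which in the WT rescue was chromosome 18 (quartiles 2.14 to 2.47, 89 regions). In both H3K4me3 lists the median fold on X equalled that of the highest autosome, and so did the median over the other autosomes.

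Narrow regions of 270 to 290 bp with a fold of at least 5 numbered 107 in the WT rescue WDR5 list, with a median width of 283 bp, and 56 of them were overlapped in all 4 lists. The H3K4me3 region of Pgk1 with a fold of 57.2 was 377 bp wide and lay at the higher-coordinate end of the gene, on X from 106203571 to 106203947.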
